A study of Escherichia coli
Acinetobacter baylyi with 6 samples.

How the data were processed

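Transcript levels were measured by RNA sequencing in 6 libraries from mixtures of the bacterium Acinetobacter baylyi (the attacking strain) and Escherichia coli MG1655 (the prey). Per the labels' protocols, both species were regrown at 30 °C to an OD600 of about 1, concentrated to an OD600 of 10 and combined in equal parts. Portions of 100 µL were placed on PTFE filters with pores of 0.45 µm and kept at 30 °C for between 10 and 30 min. RNA was taken directly from the filters, depleted of ribosomal RNA and made into stranded Illumina libraries. The time of each single library within the range of 10 to 30 min is not given in the sources used here.

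The authors deposited a table with 1 row per feature, 6 columns of scaled read counts (1 per library) and 3 columns of their own comparison, named logFC, PValue and FDR per the file headers. The submitters' processing notes name Bowtie, a short-read aligner, and edgeR, a package for count data. Versions, aligner settings, the read counter, the genome build and the annotation are not given in the sources used here. The deposited scaled read counts resemble CPM. In every library, 100% of the values were whole multiples of 1 step within 0.1 of a step. The columns summed to between 1014876 and 1191610, as counts per 1e6 reads divided by a library-specific factor could. Dividing by the step recovered whole reads: 7761919, 4156298 and 7184194 in T6SS-deficient replicates 1, 2 and 3, and 5391264, 6802586 and 7038525 in tae1-only replicates 1, 2 and 3. A count of 3 reads corresponded to scaled values of 0.424 to 0.766. Confidence intervals on reads cover counting error only, because reads were summed over the libraries of a group and the spread between libraries was left out. PCR copies were not marked, so even the counting error may be understated. The deposited log2 fold changes had the sign of the tae1-only mean minus the T6SS-deficient mean in all 394 rows that the authors' deposited table called at an adjusted p-value below 0.05. Benjamini-Hochberg adjustment of the deposited p-values gave the deposited FDR within 1% in 3241 of 3241 rows.

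The table held 3241 rows: 3151 numbered ACIAD locus tags, 17 rRNA rows, 68 tRNA rows and 5 rows with other identifiers. Reads from E. coli were not analysed here. The table pairs no locus tag with a gene name, and no A. baylyi annotation was used here, so tags are given as deposited. Of the 24 gene lists fixed before the data were examined, 23 were defined by gene symbols or products (for example the DNA damage response, competence, the type VI secretion system, ribosomal proteins and E. coli-only genes) and could not be matched. The rRNA and tRNA list was matched from the row names, which state the RNA and, for tRNA, the amino acid. For the same reason the parts of the rule for named genes that need a symbol were not applied. The rule that was applied names the deleted genes given in the genotypes. It also names, by identifier, the tags with the largest rise and the largest fall among those with an adjusted p below 0.05 and a mean log2 value of at least 5, leaving out the genes deleted in the tae1-only strain and their direct neighbours. The gene deleted in the T6SS-deficient strain could not be left out, because the table gives no tag for it. The planned limit of 3 tags per direction was lowered to 2 after the files had been seen, which left out 1 tag in each direction. In the list, up to 4 rows with the smallest p are named.

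The plan named edgeR's quasi-likelihood test, which was not run, for a table of counts, and for scaled values only it named limma with a mean-variance trend on log2(value + 1). The deposited values are scaled, so the main fit used limma (version 3.58.1, R 4.3.3) with group as the only term. The pseudocount of 1 means that fold changes of weakly expressed rows are understated. The plan set no filter for scaled values; rows needed a value of at least 1 in at least 3 libraries, and 3233 rows were tested and 8 were not. All p-values are two-sided and were adjusted by Benjamini and Hochberg's method, with calls made below 0.05. The list was tested with camera at a preset correlation of 0.01 between rows, again with an estimated correlation, and with fry. The edgeR test could have been run on the recovered reads as an alternative but was not, and no DESeq2 fit was run. The reason is that the program that checks units before that tool may be used could not read this table, whose header pads its separators with spaces. The units were therefore entered without a standard name and checked by hand. Limma-voom on the recovered reads stands in for a count-based fit. The pipeline was tested on simulated data. Reads were drawn for the 3233 rows from the observed means and library sizes, with 100 rows changed by a factor of 2 and 100 by a factor of 4. Their spread was estimated from reads not corrected for depth, so differences in depth between libraries counted as spread. Of the 100 rows changed by a factor of 2, 8% were called, and of the 100 changed by a factor of 4, 69% were called; 3 of 3033 unchanged rows were called. The simulated spread was probably wider than that of the scaled values, so these shares probably understate what the fit can call. Rows were drawn independently, whereas in the data 1 component held 68.8% of the variance within groups. The simulation therefore says little about false calls of rows that move together.

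Replicates of a group differed by far more than sampling noise, with chi-square values of 14.0 to 168 per degree of freedom between pairs, so all 6 libraries were kept as separate samples. Nothing in the labels says that they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Replicate numbers are shared between the groups. Alternatives were other scalings, pseudocounts, filters, thresholds, limma-voom on the recovered reads, the replicate number as a block, leaving out the genes deleted in the tae1-only strain with their neighbours, and leaving out each library. All were chosen before the data were examined except scaling by library totals, the authors' deposited calls, and the split of the RNA list into rRNA and tRNA. Figures were drawn with matplotlib 3.10.9.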

Results

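The data comprised 6 transcriptome libraries of A. baylyi sampled while in contact with E. coli prey on filters. A. baylyi uses a type VI secretion system (T6SS), a contractile, syringe-like machine, to push toxic effector proteins into neighbouring cells. In 3 libraries (tae1-only) the attacker carried Tae1, an effector of the amidase class that cuts peptidoglycan, as its sole remaining effector, because 4 other genes were deleted. In the other 3 libraries (T6SS-deficient) the attacker lacked tssM, which encodes a membrane component the secretion system needs. Both strains carried fluorescent fusions of VipA and ClpV, parts of the secretion machine. The comparison asks how transcript levels of A. baylyi differ when it can attack its prey with Tae1 and when it cannot attack. The strains also differ in the deleted genes themselves, and all 6 libraries held prey. Effects of attack and of genotype therefore cannot be told apart. The libraries held 4156298 to 7761919 reads on A. baylyi features.

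The genes deleted from the tae1-only strain were compared first. Of the 4 tags listed in its genotype, 3 had a row, and all 3 fell to under 3% of their level in the other strain. ACIAD3114 fell from 661 ± 72.3 (SD, n = 3) scaled reads in T6SS-deficient libraries to 10.6 ± 3.02 in tae1-only libraries, a log2 fold change of -5.86 ± 0.21 (SE, limma adjusted p = 4.19e-06). ACIAD1790 fell from 253 ± 64.1 to 6.51 ± 0.737 scaled reads, a log2 fold change of -5.05 ± 0.21 (limma adjusted p = 7.65e-06). ACIAD3425 fell from 153 ± 65.6 to 2.40 ± 0.789 scaled reads, a log2 fold change of -5.42 ± 0.35 (limma adjusted p = 5.64e-05). The remaining signal was 1.61%, 2.57% and 1.57% of the T6SS-deficient mean for ACIAD3114, ACIAD1790 and ACIAD3425. It rested on 191, 113 and 43 reads summed over 3 libraries. ACIAD0053, the other deleted tag, was not analysed here. The table pairs no tag with the name tssM, so the deletion in the T6SS-deficient strain was not checked by name. ACIAD2684 was nearly absent from that strain, at 0.511 to 1.70 scaled reads against 1809 to 2033 in tae1-only libraries. That is 0.0485% of the tae1-only mean, less than was left of the 3 deleted tags above. Whether ACIAD2684 is the gene deleted there, in which case its difference is no response to attack, cannot be told from the files.

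The 8 tags directly before and after the deleted ones in number were all lower in tae1-only libraries, but none passed the test. The tag after ACIAD3425 had 134 ± 64.8 scaled reads in T6SS-deficient and 42.6 ± 9.40 in tae1-only libraries (limma adjusted p = 0.0528). The tag before ACIAD1790 had 102 ± 31.3 and 51.8 ± 7.77 (limma adjusted p = 0.0556). The tag before ACIAD3114 had 386 ± 56.3 and 269 ± 33.9 (limma adjusted p = 0.0867).

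Across the transcriptome, 63 rows were higher and 160 were lower in tae1-only than in T6SS-deficient libraries, out of 3233 tested by limma at an adjusted p below 0.05. The falls include the 3 deleted tags with a row, and the rises include ACIAD2684. Without the genes deleted in the tae1-only strain and their neighbours, 62 rows were higher and 155 lower. The median called rise was 1.35 and the median called fall was -1.27 on the log2 scale. Of the rises, 46 reached a log2 change of 1 and 15 reached 2. Of the falls, 108 reached a log2 change of 1 and 33 reached 2. The median over all tested rows was -0.01 with the deposited scaling, which itself centres most rows, and -0.08 with library totals, so a shift of the whole transcriptome cannot be read from these values. Among the 63 rises and 160 falls, the 3 libraries of one group did not overlap the 3 of the other in any case. Such separation was found in 33.5% of all tested rows. For a single row it has a chance of 10%. Rows moved together, so the share in 1 data set could lie far from 10% by chance.

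ACIAD2684, whose level in T6SS-deficient libraries is as low as that of a deleted gene, had the largest called positive difference, from 1.70, 0.511 and 0.565 scaled reads in T6SS-deficient replicates 1, 2 and 3 (12, 2 and 4 reads) to 1907 ± 114 (SD, n = 3) in tae1-only libraries. Its summed reads were 33261 and 18, and their ratio after correction for the scaling of the libraries was 1926 with an exact 95% interval of 1219 to 3251 that covers counting error only. Its log2 fold change was 10.01 ± 0.23 (SE, limma adjusted p = 4.95e-07), and 10.90 in the authors' deposited table. ACIAD1170 rose from 30.9 ± 1.15 to 429 ± 34.1 scaled reads, 13.9-fold, with a log2 fold change of 3.75 ± 0.12 (limma adjusted p = 3.55e-06). ACIAD1170 lay between 29.6 and 31.9 scaled reads in the 3 T6SS-deficient libraries. The baseline of ACIAD2684 rests on 18 reads, and its log2 fold change ran from 8.34 with a pseudocount of 5 to 11.03 with limma-voom on the recovered reads.

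Among tags eligible for naming (mean log2 value of at least 5), ACIAD3338 had the largest called fall outside the deleted genes and their neighbours. It fell from 1018 ± 143 to 52.4 ± 4.28 scaled reads, 19.4-fold lower, with a log2 fold change of -4.25 ± 0.15 (limma adjusted p = 3.70e-06). ACIAD3463 fell from 918 ± 746 to 70.3 ± 20.2 scaled reads, with a log2 fold change of -3.35 ± 0.58 (limma adjusted p = 0.0149). Its T6SS-deficient values were spread widely, at 281, 734 and 1738 in replicates 1, 2 and 3, and its call was lost without T6SS-deficient replicate 2 (limma adjusted p = 0.0871), without tae1-only replicate 1 (0.0683) and without tae1-only replicate 2 (0.0545). The log2 fold change stayed at -3.33, -3.23 and -3.26 in these fits. It moved more, to -2.71 without T6SS-deficient replicate 3 and -4.02 without T6SS-deficient replicate 1, where the call was kept. Wider spread in T6SS-deficient libraries was general. The median SD of log2 values was 0.25 in T6SS-deficient and 0.16 in tae1-only libraries over all tested rows. Over the called falls it was 0.36 and 0.20, and over the called rises 0.22 and 0.13.

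**Figure D1:**
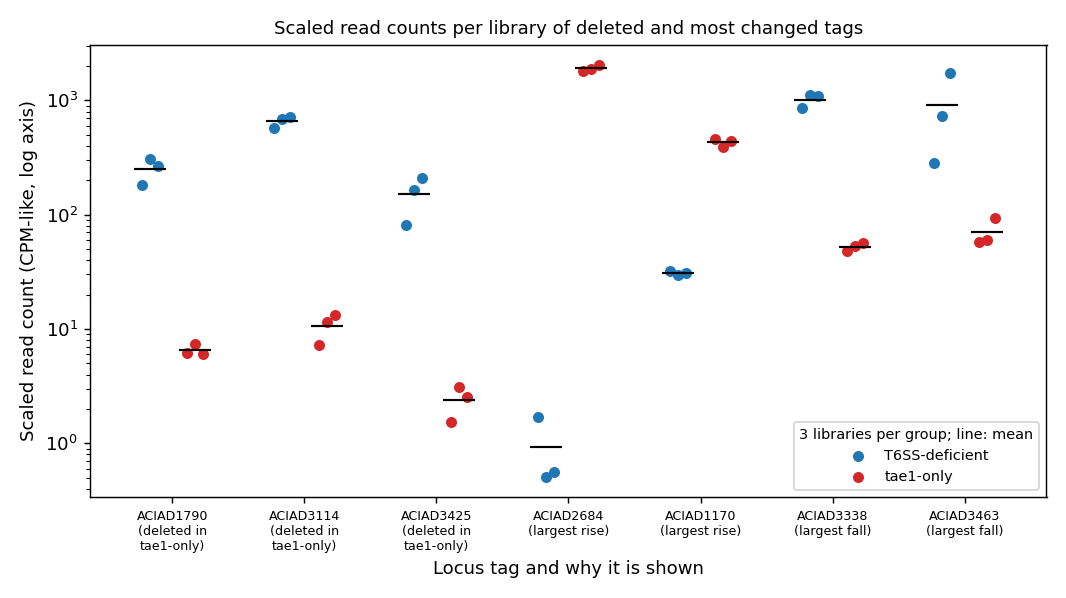
Scaled read counts (CPM-like, log axis) per library for the 3 deleted tags with a row. Also shown, among tags eligible for naming, are the 2 with the largest rise and the 2 with the largest fall. Points are the 3 libraries of each group, drawn in replicate order, and lines are means; ACIAD2684 lies at 1.70 or less in T6SS-deficient libraries and near 1907 in tae1-only libraries, and ACIAD3463 spreads from 281 to 1738 within the T6SS-deficient group.

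The counts of called rows depended on single libraries. Without T6SS-deficient replicate 1, 538 rows were higher and 683 lower. Leaving out any of the other 5 libraries gave 41 to 54 higher and 49 to 85 lower. The lowest of these, 41 and 49, came without tae1-only replicate 1. Without T6SS-deficient replicate 2 the counts were 42 and 52, without T6SS-deficient replicate 3 they were 54 and 85, without tae1-only replicate 2 they were 44 and 71, and without tae1-only replicate 3 they were 44 and 56. No called row changed sign in any of these fits. That outcome was fixed in advance, because the groups did not overlap in any called row. The authors' deposited table called 88 rows higher and 306 lower at an adjusted p below 0.05. Of the calls made here, 57 of the 63 rises and 144 of the 160 falls were also called there, and none was called in the opposite direction.

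**Figure D2:**
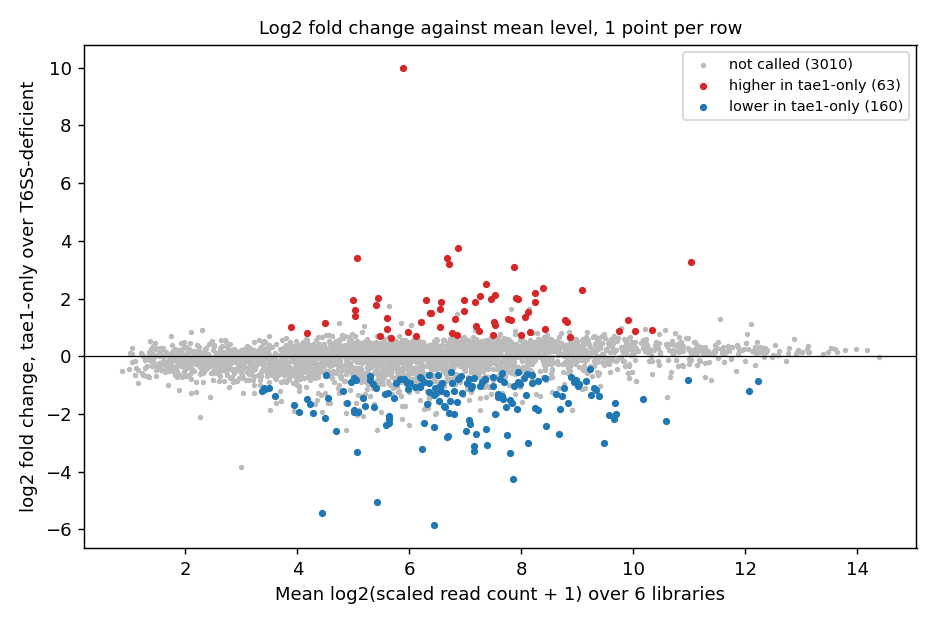
Log2 fold change (tae1-only over T6SS-deficient) against the mean log2(scaled read count + 1) over the 6 libraries, 1 point per tested row. Red points are the 63 rows called higher, blue points the 160 called lower and grey points the rest; the point at 10.01 is ACIAD2684 and the 3 blue points below -5 are the deleted tags.

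Ribosomal and transfer RNA formed the gene group that could be identified from the row names. Of its 85 rows (17 rRNA and 68 tRNA), 1 passed the test over all rows and none passed when adjusted over the list alone. The row that fell was a tRNA-Ile copy (number 42), from 41.2 ± 8.31 (SD, n = 3) to 23.9 ± 2.20 scaled reads, with a log2 fold change of -0.75 ± 0.18 (SE, limma adjusted p = 0.0491). The rows next in rank were a tRNA-Pro copy (number 21) with 7.91 ± 1.42 in T6SS-deficient and 13.4 ± 1.60 in tae1-only libraries, a tRNA-Ile copy (number 76) with 248 ± 71.5 and 150.0 ± 10.1, and a tRNA-Arg copy (number 67) with 121 ± 23.5 and 82.2 ± 1.74. None of these passed the test (limma adjusted p = 0.0648, 0.0825 and 0.0868). All 7 tRNA-Ile rows had negative log2 fold changes, from -0.75 to -0.36, and their sum was 666 ± 166 scaled reads in T6SS-deficient and 447 ± 52.3 in tae1-only libraries. Copies of one tRNA can share reads, so values of single copies are uncertain and the copies are not independent. Whether reads of E. coli from the mixture entered the rRNA and tRNA rows cannot be told, because aligner settings are not given.

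All 7 16S and all 7 23S rRNA rows had positive log2 fold changes, with medians of 0.39 and 0.41, while 2 of the 3 5S rRNA rows had negative ones, with a median of -0.18 over the 3. None of the 17 passed the test. The libraries had been depleted of ribosomal RNA, so these rows hold what depletion left and cannot be read as transcript levels. They also moved together (estimated correlation 0.83), so they are not independent. The summed rRNA rows made up 0.0509% of reads in tae1-only replicate 1 and 0.0198% to 0.0296% in the other 5 libraries. As a set, the 85 rows were not shifted detectably (camera p = 0.404 with the preset correlation, p = 0.839 with an estimated correlation; fry directional p = 0.825). The 17 rRNA rows alone gave camera p = 0.0455 with the preset correlation and p = 0.598 with an estimated correlation. The 68 tRNA rows alone gave camera p = 0.895 with the preset and p = 0.974 with an estimated correlation, with a median log2 fold change of 0.02 and a mean of -0.03. Their fry p for a change in either direction was 0.0321. The split into rRNA and tRNA was made after the data had been seen, and these p-values were not adjusted for the 3 sets tested.

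**Figure D3:**
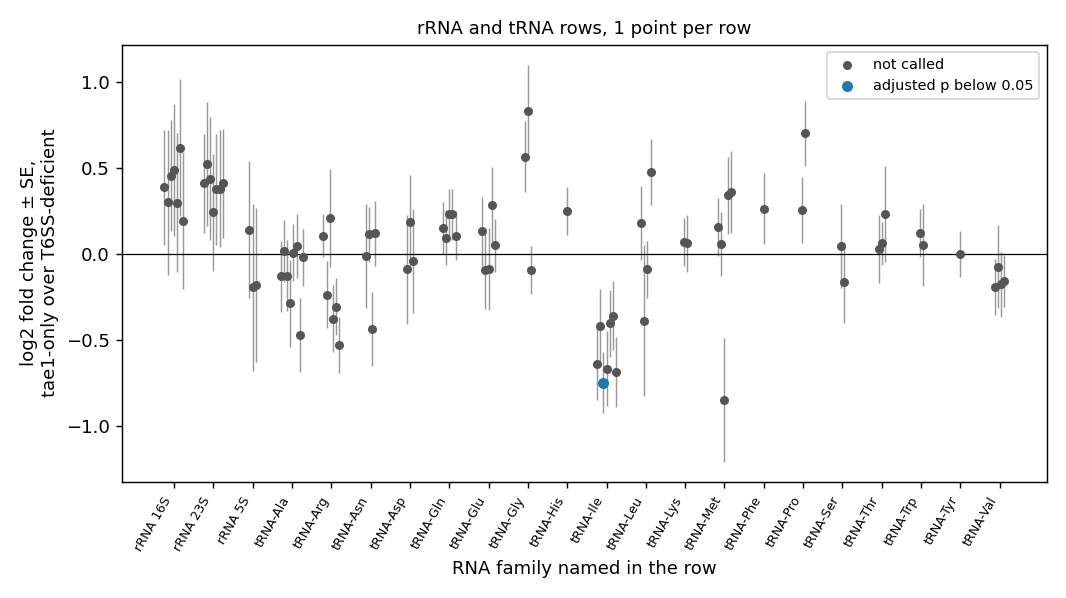
Log2 fold change (tae1-only over T6SS-deficient) with its SE for each of the 85 rRNA and tRNA rows, grouped by the RNA named in the row. The single blue point is the tRNA-Ile copy that passed the test at -0.75, and the 7 tRNA-Ile points all lie below 0.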

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

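The counts of 63 rises and 160 falls moved with several settings, and no called row changed sign under any. For the fits without 1 library and for other pseudocounts this was fixed in advance, because the groups did not overlap in any called row. It was also fixed for the block, the filters and the thresholds, which keep the same log2 fold changes. Only other scalings, limma-voom and the authors' deposited table could have changed a sign. The replicate number as a block gave 388 rises and 559 falls, including all 63 and all 160, and an adjusted p below 0.1 gave 157 and 350. An adjusted p below 0.01 left 42 rises and 48 falls. Falls numbered 106 with limma-voom on the recovered reads and 306 in the authors' deposited table. Leaving out 1 library at a time gave 41 to 538 rises and 49 to 683 falls, with the largest move, to the highest values, without T6SS-deficient replicate 1. The replicate numbers did not meet the criterion for pairing, that each library correlate best with its own number. Deviations from the group mean correlated at 0.62, 0.06 and 0.48 for numbers 1, 2 and 3. The libraries numbered 2 did not correlate best with each other. Both lay near the middle of the component holding 68.8% of the variance within groups (scores 0.09 in T6SS-deficient, 0.03 in tae1-only). Their low correlation therefore cannot decide against pairing. Rises made up 28.3% of calls, 38.3% to 45.6% with any 1 library left out, 41.0% with the block, 46.7% below 0.01 and 22.3% in the authors' deposited table. Counts stayed within 1.5 times under the other settings, including median-of-ratios scaling (67 and 198) and library totals (57 and 119). The RNA list's direction, never past the threshold with all rows, turned with only rows of a mean log2 value of at least 5 (camera with the preset correlation, p = 0.831), without T6SS-deficient replicate 3 (p = 0.250) and without tae1-only replicate 1 (p = 0.656); its p ranged from 0.0501 to 0.656 over the left-out libraries, and rRNA rows alone gave p = 0.0455, or 0.598 with an estimated correlation. Of the 7 named tags, 6 kept direction and call throughout and ACIAD3463 lost its call in 3 fits. A DESeq2 test was not run. Depth was at least 4156298 reads. In simulation with the observed depth and 3 replicates, 8% of changes by a factor of 2 were called. Its spread also held differences in depth between libraries, so that share is probably too low.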

Other observations

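The tests of tag neighbourhood, of tRNA-Ile, of the pairing of replicate numbers, of disjoint libraries and of other splits were chosen after the results were seen; those of left-out replicate sets, of depth and of chromosome position were fixed before their results were seen.

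Called tags clustered along the numbering. Of the 222 called numbered tags, 132 stood beside another tag called in the same direction, counting tags in order of their number among those tested. There were 86 such adjacent pairs, against a mean of 9.25 and a highest value of 22 in 10000 random placements (permutation p = 0.0001, the smallest these placements can give). Runs of 3 or more numbered 5 among rises and 14 among falls. The longest run of rises had 7 tags with log2 fold changes from 0.81 to 3.09 and a median of 1.90. The longest run of falls had 11 tags, ACIAD3338 among them, from -4.25 to -0.79 with a median of -1.02. Transcription of neighbouring genes as units is a candidate explanation that strand and operon annotation, not used here, would test.

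A gradient around the chromosome was not detected. The first harmonic of the log2 fold change over tag order had an amplitude of 0.04, and shuffled blocks of 20 tags gave a value as large with permutation p = 0.340. The negative values of all 7 tRNA-Ile rows, tested as a set chosen after it was seen, gave a fry directional p of 0.0616.

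The first pattern that invites a closer look is the excess of falls over rises, given the wide spread among T6SS-deficient libraries. Rows called on 2 replicate sets were checked in the set left out, whose libraries had no part in the calls. The share moving the same way was at least 96.7% for falls and 98.9% for rises. That argues against 1 replicate set as the source of the direction of these calls. It does not test the excess of falls over rises. With replicate set 1 left out, 469 of 485 falls went the same way with a median of -0.62, against -1.06 in the libraries that called them. Calls numbered 268 rises and 485 falls without set 1, 23 and 25 without set 2, and 47 and 61 without set 3. The size of the excess of falls therefore depended on the set left out. The real grouping called 63 rises and 160 falls. The other 9 of the 10 splits of the 6 libraries into 3 and 3 called at most 0 in either direction. Thus 1 of 10 splits gave as many rises and 1 of 10 as many falls, and 10 splits are too few for a share under 0.05. Each other split mixes the groups, so their difference widens the spread within its parts and few calls are to be expected.

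The second pattern is a difference between replicates 1 and 3 that both groups share. Across genes, which are not independent replicates, replicate 3 minus replicate 1 correlated at 0.62 between the groups, and 1 component held 68.8% of the variance within groups. Thinning each library to 4156298 reads left a correlation of 0.57. Thinning leaves the expected scaled values unchanged, so it is a weak test of depth. From replicate 1 to replicate 3, depth fell in T6SS-deficient libraries (7761919 to 7184194 reads). It rose in tae1-only libraries (5391264 to 7038525 reads), which argues against depth as the source of a difference in the same direction. In disjoint libraries, replicate 3 minus replicate 1 correlated with the difference between the groups in replicate 2 at -0.63 in T6SS-deficient and -0.45 in tae1-only libraries, so rows lower with tae1 tended to be higher in replicate 3 than in replicate 1. One hypothesis is that libraries differed in incubation time within 10 to 30 min or in growth state, along the genes that also separate the groups. A shared culture or day by number remains open, because own numbers gave the highest mean correlation (0.38, next 0.31) but 1 of 6 pairings is the smallest share possible; the sources used here give no time or day per library. Libraries of both strains sampled at set times, with growth state, culture and day recorded, would test both. The difference in genotype and attack between the groups stays an untested biological explanation.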
